A study of Mus musculus with 38 samples.

How the data were processed

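RNA of sorted CD11b+ cells was measured on Affymetrix Gene 1.0 ST arrays, 38 in all, for 13 populations of female C57BL/6 mice aged 6 weeks. Per the labels, ear skin was treated with 10 µl of 0.5% DNFB 3 days before harvest, 5000 to 10000 cells gave 5 to 20 ng of RNA, and this was amplified before hybridisation. Each population has 3 arrays from independent pools of mice, except dermal P1 after DNFB with 2. The series describes 3 chip batches without saying which array belongs to which, so no fit with a batch term could be made. Groups were taken from titles and characteristics. The CD64+ lymph node cells were kept as their own group, as their fields name them differently.

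The deposited values are log2 intensities per probe set, which the authors summarised and normalized with RMA and the affy package, per the submitters' processing notes, with no versions given. The 34760 probe sets have values from 1.65 to 13.8 and array medians from 4.39 to 4.65. Each array has a column of its own, so no replicates were pooled. The values were not scaled or log-transformed further. No raw intensities were read, so background correction and probe filtering are the authors'. Correlation between replicates of a group lay between 0.947 and 0.993.

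Probe sets with 1 gene symbol (21640) were kept, 1321 with several symbols and 11799 with none were left out, and of the kept ones 21553 could be matched to a RefSeq gene by their gene identifier. Where a gene had more than 1 probe set (954 genes), the one with the highest mean was used, which left 19937 genes. The Ly6C genes share probe sets with several symbols and are not named, although Ly6C was a sort marker.

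A linear model with a mean for each of 13 groups was fitted in limma 3.58.1 under R 4.3.3 (tables read with the data.table package, version 1.17.8), with moderated t tests (25 residual and 3.13 prior degrees of freedom). Of 17 comparisons 15 are differences of groups and 2 are differences of DNFB effects. Adjustment was by Benjamini-Hochberg over 19937 genes for each comparison, and a gene rose or fell at an adjusted p under 0.05. Named genes are up to 6 rises and 6 falls per comparison, ranked by size among genes whose arrays do not overlap between groups, up to 5 members per gene list by smallest adjusted p, and the sort markers. A p of small groups rests on the variance pooled over all arrays by limma, since a permutation of 3 against 3 arrays has 10 splits and cannot pass. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

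The 31 gene lists cover MHC class II presentation, classical monocyte, macrophage core, tissue-resident macrophage, conventional DC core, CD11b+ DC, DC maturation and migration, cDC1 and Langerhans cell, interferon response, inflammatory cytokines and mediators, alternative activation, glycolysis, cell cycle, lysosome, scavenger and efferocytosis receptors, complement, cholesterol synthesis, NF-kB targets, immediate early and dissociation stress, chemokine receptors, pattern recognition receptors, and keratinocyte, fibroblast, endothelial cell, T cell, B cell, NK cell, neutrophil, mast cell and basophil, plasmacytoid DC, and erythroid and platelet genes. They were written from general knowledge, and 33 genes sit on 2 lists and 1 on 3. Each list was tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over all 527 tests, of which 246 passed, and 113 passed with the correlation estimated for each list. Counts of members are given adjusted over all genes and over the list alone.

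The groups, comparisons, tests, gene lists, named-gene rule and the alternatives were fixed before the data were examined, apart from the fits with keratinocyte and fibroblast list means as covariates, which were added later. A list of 20 cartilage genes and the tests of technical explanations, some with bounds chosen after the result was seen as stated beside them, were added later too. The alternatives fixed in this way were the replicate number as a fixed block, the number of the source name as a random block, quantile normalization, centring of array medians, leaving out low values, the mean of all probe sets of a gene, all probe sets, an intensity trend with robust variances, array weights, fitting only the compared groups, leaving out 1 array at a time, a change of at least 2-fold, and, for the lists, the estimated correlation and the removal of members shared with another list.

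The method was tested on simulated data with the group sizes of the study. Of 100 genes changed 2-fold it found 62 for DNFB in P1, 69 for DNFB in P2, 75 for P3 against P2 and 71 for lymph node against dermal DC, and of 100 changed 4-fold it found 91, 98, 95 and 97. Unchanged genes called were 4, 7, 11 and 5, and 0 went in the wrong direction. Camera called the 1 raised list of 31 and 0 others, which leaves the preset correlation untested.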

Results

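The arrays cover 13 sorted populations of CD11b+ myeloid cells, taken from blood, ear dermis and lymph node of C57BL/6 mice at steady state or 3 days after 2,4-dinitrofluorobenzene (DNFB), a contact sensitiser. Dermal monocyte-like cells were sorted as P1 (CD64low, Ly6Chi, MHC II negative), P2 (CD64+, Ly6Chi, MHC II+) and P3 (CD64+, Ly6Clow, MHC II+), macrophages as P4 (MHC II negative) and P5 (MHC II+), and dermal dendritic cells (DC) as CD64-negative, MHC II+ cells. Populations have n = 3 arrays, P1 after DNFB n = 2. Differences are log2 values with the standard error (SE) and folds their antilogs. Levels are group means of log2 values with the standard deviation (SD). Each p is from limma, adjusted over 19937 genes. No detection calls exist. A change whose lower level is under 4.02, the 40th percentile of all values, has low signal and no exact size. This may hold near 4.43, the keratinocyte list mean in blood.

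**Figure D1:**
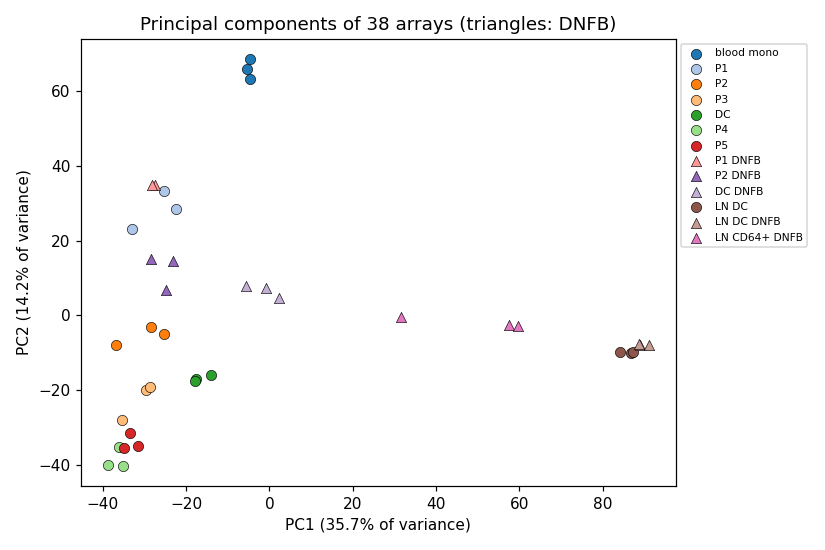
Principal components 1 and 2 of 38 arrays over 19937 genes, 1 point per array, triangles for DNFB and circles for steady state, axes in component units. Lymph node DC lie farthest to the right and blood monocytes at the top, with component 1 holding 35.7% and component 2 holding 14.2% of the variance.

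Dermal P1 cells, compared with blood monocytes, held far more RNA of secreted mediators and far less of interferon-induced genes. Il6, a cytokine of acute inflammation, was 44.5-fold higher in P1 (5.47, SE 0.46, adjusted p = 8.1e-10). Its level was 8.41 (SD 0.48), against 2.94 (SD 0.12) in blood. Il1a, which encodes interleukin-1 alpha, was 17.8-fold higher (4.15, SE 0.37). Ccl7, which attracts monocytes, rose 23.8-fold (4.58, SE 0.45), and Il10, which restrains inflammation, 21.8-fold (4.45, SE 0.34). Cxcl1, which attracts neutrophils, rose by 2.98 (SE 0.27). The tetraspanin gene Cd63 rose 86.6-fold (6.44, SE 0.28), the metallothionein gene Mt2 71.6-fold (6.16, SE 0.29) and Emp1 57.4-fold (5.84, SE 0.19). Usp18, a brake on interferon signalling, was 12.4-fold lower (-3.63, SE 0.28, adjusted p = 2e-10), and Ifit3b 16.2-fold lower (-4.02, SE 0.28). Ifi206, Ifit2 and Oas3 fell by 3.28, 2.73 and 2.12. Il6, Il1a, Il10 and Cd63 had low signal in blood and Ifit3b in P1. Of 23 interferon response genes 0 rose, 19 fell and 4 did not pass. When adjusted over the list alone 20 fell, and the list passed the camera test (adjusted p = 1.3e-20). Among 24 inflammatory mediators 13 rose, 1 fell and 10 did not pass (13 and 2 adjusted over the list alone, adjusted p = 1.1e-12). Of 15 NF-kB targets, Nfkbie and Tnip1 among them (1.72, SE 0.20, and 1.30, SE 0.18), 9 rose and 0 fell (11 and 0 adjusted over the list alone, adjusted p = 9.4e-11).

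Some genes of DC maturation and of tissue-resident macrophages were also higher in P1 than in blood. Cd83, a marker of activated DC, rose 10.7-fold (3.41, SE 0.25), the costimulator gene Cd86 by 2.15 (SE 0.26), and Ccr7, whose product guides cells to lymph nodes, by 1.24 (SE 0.27). The mannose receptor gene Mrc1 rose by 2.35 (SE 0.31), the chemokine gene Pf4 by 3.03 (SE 0.46) and C1qc, which encodes a chain of complement C1q, by 2.49 (SE 0.42). In the DC maturation list 7 of 25 rose and 0 fell (8 and 1 adjusted over the list alone, adjusted p = 0.00043, and adjusted p = 0.21 with an estimated correlation). In the tissue-resident macrophage list 8 of 25 rose and 0 fell (8 and 0 adjusted over the list alone, adjusted p = 1.4e-05, adjusted p = 0.27 with an estimated correlation, and 0.14 without the members on another list). Of 16 alternative activation genes 5 rose and 0 fell (5 and 0 adjusted over the list alone, adjusted p = 0.00061). The other lists of these cells did not pass. MHC class II genes gave 1 rise and 1 fall among 10 (the same adjusted over the list alone, adjusted p = 0.96, the median, mean and test differing in sign). Conventional DC core genes gave 4 and 5 among 24 (6 and 5 adjusted over the list alone, adjusted p = 0.91). CD11b+ DC genes gave 0 and 2 among 13 (1 and 3 adjusted over the list alone, adjusted p = 0.6, the median, mean and test differing in sign). Macrophage core genes gave 5 and 6 among 32 (5 and 9 adjusted over the list alone, adjusted p = 0.3). The immediate early list split, with Ier3 up by 3.57 (SE 0.18) and Egr1 down (-1.79, SE 0.29, adjusted p = 0.056 when only these groups were fitted). It had 4 rises and 7 falls among 20 (5 and 7 adjusted over the list alone, adjusted p = 0.7, the median, mean and test differing in sign). Fcgr1, the gene of CD64, fell by 1.35 (SE 0.34, adjusted p = 0.0077), Ccr2 by 0.84 (SE 0.27, adjusted p = 0.041, a call lost without any 1 of the 6 arrays, at 0.06 to 0.12). Itgam, the gene of CD11b, differed by -0.45 (SE 0.22, adjusted p = 0.21). Genes of other skin cells stood beside these: Dcn, a matrix proteoglycan gene of fibroblasts, was 119-fold higher (6.90, SE 0.45) and Krt5, a keratin gene of the basal epidermis, 38.4-fold higher (5.26, SE 0.40). In all, 11 of 14 keratinocyte genes rose (14 adjusted over the list alone, adjusted p = 2e-18) and 10 of 12 fibroblast genes rose (12 adjusted over the list alone, adjusted p = 4.1e-16). Of 12 endothelial cell genes 2 rose (4 adjusted over the list alone, adjusted p = 0.013, adjusted p = 0.23 with an estimated correlation, and 0.072 without replicate 3 of P1). Altogether 1038 genes rose and 1482 fell, a rising share of 41.2% that was 29.1% with array medians centred. The count of 2520 was 292 with the keratinocyte and fibroblast list means as covariates, 61.6% of them rising, and 1343 when only these groups were fitted. Those covariates ended the calls of Fcgr1 (-0.40, adjusted p = 0.94), Ccr2 (-0.43), Ccr7 (0.68), Cd86 (1.7) and Ifi206 (-2.08), and of C1qc without shrinking it (2.90), and tissue and digestion differ along with the cell population.

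**Figure D2:**
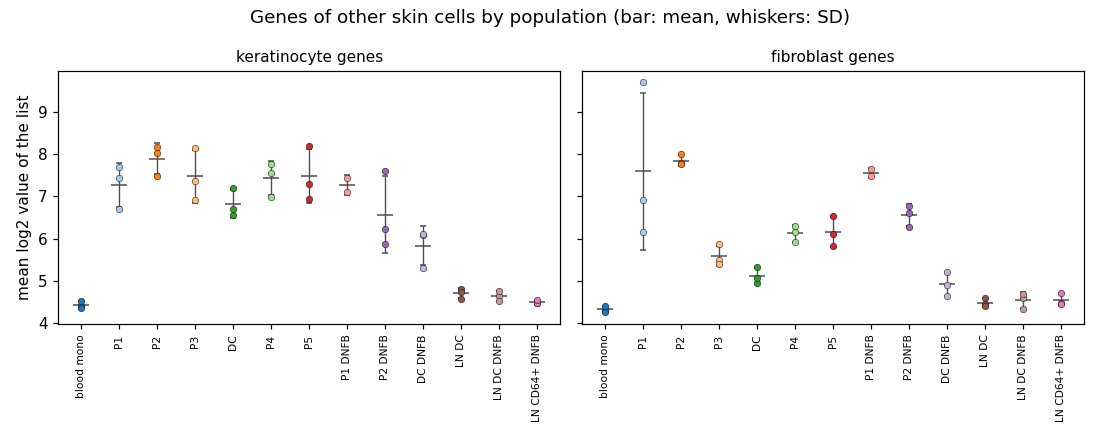
Mean log2 value of the 14 keratinocyte genes and of the 12 fibroblast genes in each of 38 arrays, 1 point per array, by population, with the bar at the group mean and the whiskers at 1 SD. Blood and lymph node arrays are low for both lists, and the dermal group means are higher, with P2 at steady state the highest group for both.

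P2 cells held more RNA for antigen presentation and for the products of alternatively activated macrophages than P1 cells. Retnla, induced by interleukin-4, was 96.6-fold higher in P2 (6.59, SE 0.45), at 10.63 (SD 0.39) against 4.04 (SD 0.93). The lectin gene Mgl2 rose 72.7-fold (6.18, SE 0.35) and Ccl17, which attracts T cells, 38.8-fold (5.28, SE 0.30). H2-Eb1, which encodes an MHC class II beta chain, rose 10.6-fold (3.40, SE 0.13, adjusted p = 5.1e-17). H2-Ab1 rose 4.05-fold (2.02, SE 0.15), H2-Aa by 2.02 (SE 0.14) and the invariant chain gene Cd74 by 1.12 (SE 0.11). Cd209d rose 32-fold (5.00, SE 0.51), the haemoglobin scavenger receptor gene Cd163 21.9-fold (4.45, SE 0.34). Fcrls rose by 4.22 (SE 0.41), C1qa by 3.27 (SE 0.38) and Mrc1 by 2.54. The DC genes Cd209a, Irf4, Ccl22 and Ccr7 rose by 3.57, 1.85, 3.84 and 1.78. Itgax, the gene of CD11c, rose by 2.42 (SE 0.20), and the proliferation genes Top2a, Mki67 and Cdk1 by 2.24, 1.63 and 1.49. Treml4 was 17.3-fold lower (-4.12, SE 0.33), Ifitm6 9.16-fold (-3.19, SE 0.52) and the haptoglobin gene Hp 8.39-fold (-3.07, SE 0.31). Pglyrp1 fell by 3.66, and Cx3cr1, the fractalkine receptor gene, fell by 2.03 (SE 0.27). Fcgr1 differed by -0.06 (adjusted p = 0.98), Ccr2 by 0.32 (adjusted p = 0.77) and Itgam by -0.42 (adjusted p = 0.51).

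Of 10 MHC class II presentation genes 7 rose in P2 and 0 fell (8 and 0 adjusted over the list alone, adjusted p = 4.2e-27). The sort gates, MHC II negative for P1 and MHC II+ for P2, chose the cells by this difference. Tissue-resident macrophage genes gave 13 rises among 25 (16 adjusted over the list alone, adjusted p = 1.6e-28). Alternative activation genes gave 8 among 16 (11, and 1 fall, adjusted over the list alone, adjusted p = 4.1e-22) and cell cycle genes 9 among 25 (18 adjusted over the list alone, adjusted p = 5.1e-20). CD11b+ DC genes gave 4 rises among 13 (5, and 1 fall, adjusted over the list alone, adjusted p = 7.3e-09) and conventional DC core genes 5 among 24 (6 adjusted over the list alone, adjusted p = 1.1e-06). In the classical monocyte list 2 of 10 fell (6 adjusted over the list alone, adjusted p = 2.5e-09). The scavenger receptor list had 2 rises among 16 (2 adjusted over the list alone, adjusted p = 0.017). The list lost its call with an estimated correlation (adjusted p = 0.42). It turned in direction without the members on another list (adjusted p = 0.126), and was 0.15 and 0.42 without replicate 3 of P1 and replicate 1 of P2. In all 268 genes rose and 148 fell, a total of 416 that was 62 when only P1 and P2 were fitted, a fit that ended the calls of Cdk1 (adjusted p = 0.057), Irf4 (0.23) and Pglyrp1 (0.16). Fcrls had low signal in P1.

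P3 cells held less RNA of circulating monocytes than P2. Plac8, a monocyte gene, was 22.2-fold lower in P3 (-4.47, SE 0.62), at 5.19 (SD 1.13) against 9.66 (SD 0.48). Hp was 11.9-fold lower (-3.57, SE 0.31, adjusted p = 7.9e-08), the chitinase-like gene Chil3 13.7-fold lower (-3.78, SE 0.52) and the versican gene Vcan 9.97-fold lower (-3.32, SE 0.32). The collagenase gene Mmp8 fell by 3.03 (SE 0.31). C1qa rose by 1.92 (SE 0.38), from 9.15 (SD 0.89) to 11.08 (SD 0.17). Il1a rose 4.08-fold (2.03, SE 0.37), the adaptor gene Blnk by 1.94 (SE 0.25), and Abcc3 and Zmynd15 by 1.89 and 1.85. Fcgr1 differed by 0.71 (SE 0.34, adjusted p = 0.55), Itgax by 0.74 (SE 0.20, adjusted p = 0.09) and H2-Ab1 by -0.04 (adjusted p = 0.98). Matrix genes of fibroblasts went down together: Postn was 17.2-fold lower (-4.11, SE 0.70). Lum, Tnfaip6 and Dcn fell by 3.66, 3.84 and 2.36, Dcn standing at 9.10 in P3 and 11.46 in P2. Of 10 classical monocyte genes 5 fell (7 adjusted over the list alone, adjusted p = 1.3e-20). Of 12 fibroblast genes 6 fell (11 adjusted over the list alone, adjusted p = 2e-23). Tissue-resident macrophage genes gave 1 rise among 25 (12 adjusted over the list alone, adjusted p = 1.3e-11, and adjusted p = 0.073 with an estimated correlation), and inflammatory mediators gave 1 among 24 (8 adjusted over the list alone, adjusted p = 6.2e-07). The count of 35 rises and 39 falls, 74 in all, was 205 with the keratinocyte and fibroblast covariates, 19 when only these groups were fitted, 124 with array weights and 167 without replicate 1 of steady-state P2. The balance turned with these settings: the rising share of 47.3% was 88.3% with the covariates, which shared 23 of the 74 genes, and 10.5% when only these groups were fitted. Without 1 array it lay between 25.4% (replicate 3 of P2) and 67.7% (replicate 1 of P2). The call of C1qa ended without replicate 2 or 3 of P2 or replicate 3 of P3 (adjusted p = 0.073, 0.11 and 0.058), and that of Il1a without replicate 3 of P2 (0.07). Those of Dcn and Lum ended without replicate 2 of P3 (0.052 and 0.067), Dcn also without replicate 1 of P3 and Lum without replicate 2 of P2 (0.059 each). With the covariates those of Abcc3 (1.45), Dcn (-0.70), Lum (-0.72), Postn (-1.05) and Tnfaip6 (-1.59) ended, and that of C1qa at the same size (1.92). When only these groups were fitted, these 6 ended as well, as did Plac8 (adjusted p = 0.097), Chil3 (0.12), Vcan (0.1), Mmp8 (0.098) and Il1a (0.2). Hp and Mmp8 had low signal in P3.

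Dermal DC held more RNA of DC genes and less of macrophage genes than P3. Flt3 was 6.76-fold higher in DC (2.76, SE 0.33), at 8.73 (SD 0.24) against 5.97 (SD 0.41). Ccr7 rose 4.05-fold (2.02, SE 0.27), Adam23 9.67-fold (3.27, SE 0.32) and Gpr141b 11.2-fold (3.49, SE 0.42). The peptidase gene Dpp4 rose by 2.95 (SE 0.42), and Ccl22 by 2.28 (SE 0.35). Kmo, an enzyme of tryptophan breakdown, rose by 2.09, P2ry10 by 2.17 and H2-Ob by 1.49 (SE 0.29). Ms4a7 was 25.4-fold lower (-4.67, SE 0.45), Mertk, a receptor for dying cells, 8.09-fold (-3.02, SE 0.49) and Fcgr1 6.78-fold (-2.76, SE 0.34). Aoah fell by 3.44 (SE 0.35), the RNA sensor gene Tlr7 by 3.14 (SE 0.39) and Msr1 by 2.73 (SE 0.30). C1qa fell by 2.63, Apoe by 2.17 (SE 0.22), Lgmn by 1.90 (SE 0.22), Il10 by 2.42, Ccl7 by 2.38 (SE 0.45) and Oasl2 by 1.79 (SE 0.30). H2-Ab1 differed by 0.12 (adjusted p = 0.95), Itgax by 0.67 (SE 0.20, adjusted p = 0.083, and 0.024 without replicate 2 of P3), Ccr2 by -0.34 (adjusted p = 0.84) and Itgam by -0.33 (adjusted p = 0.74). Of 32 macrophage core genes 0 rose and 13 fell in DC (19 falls adjusted over the list alone, adjusted p = 1.8e-26). Of 25 tissue-resident macrophage genes 1 rose and 14 fell (2 and 16 adjusted over the list alone, adjusted p = 9.4e-23), and of 24 conventional DC core genes 7 rose (9 adjusted over the list alone, adjusted p = 8.9e-14). Falls also outnumbered rises among pattern recognition receptors (0 and 9 of 21, 1 and 12 adjusted over the list alone, adjusted p = 4.6e-17) and inflammatory mediators (0 and 9 of 24, 0 and 12 adjusted over the list alone, adjusted p = 1e-12). The same held for interferon response genes (0 and 5 of 23, 0 and 10 adjusted over the list alone, adjusted p = 1.4e-11), scavenger receptors (1 and 6 of 16, 2 and 8 adjusted over the list alone, adjusted p = 1.4e-09) and complement genes (0 and 5 of 12, the same adjusted over the list alone, adjusted p = 1.4e-09). In total 149 genes rose and 209 fell, 41.6% rising (55.6% without replicate 3 of P3). The sum of 358 was 101 with only DC and P3 fitted. That fit ended the calls of Ccl22 (adjusted p = 0.063), H2-Ob (0.16), Kmo (0.13), Oasl2 (0.072) and P2ry10 (0.063). Gpr141b had low signal in P3 and Mertk in DC.

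P4 and P5 macrophages, taken as the mean of both, stood far apart from dermal DC. Ccl8, a monocyte-attracting chemokine gene, was 170-fold higher in macrophages (7.41, SE 1.04), at 12.23 (SD 0.16) in P4 and 12.17 (SD 0.11) in P5 against 4.80 (SD 1.59). Ms4a7 was 69.9-fold higher (6.13, SE 0.39), the endothelin receptor gene Ednrb 42.4-fold and the scavenger receptor gene Stab1 25.6-fold (4.68). Lyve1, a hyaluronan receptor gene of perivascular macrophages, rose 25-fold (4.65, SE 0.44), C4b 19.5-fold (4.29, SE 0.31), Mertk 17-fold (4.08, SE 0.43) and Fcgr1 6.36-fold (2.67, SE 0.30). Folr2, Cd209f, Tlr7, Msr1, C5ar1, C1qa, Cx3cr1, Apoe and Lgmn rose by 5.22, 5.30, 3.90, 3.40, 3.39, 3.19, 2.77, 2.50 and 2.52. In DC, Klrb1b stood 31.6-fold above macrophages (-4.98 as macrophages minus DC, SE 0.28), Slc27a3 26-fold (-4.70, SE 0.23) and Ccl17 19.9-fold (-4.32, SE 0.26). Itgax stood 9.22-fold higher in DC (-3.20, SE 0.17), Ccr7 7.85-fold (-2.97, SE 0.23) and Flt3 7.83-fold (-2.97, SE 0.29). H2-Ab1, Ccr2, Dpp4 and Top2a were lower in macrophages as well (-1.28, -1.68, -3.43 and -1.79). Ccl17 divided the macrophages, at 4.94 in P4 and 10.90 in P5 beside 12.24 in DC. So did H2-Ab1, at 9.63 in P4, 11.85 in P5 and 12.02 in DC, the mean of both macrophages resting on the MHC II-negative P4. Ednrb, Mertk and Cd209f had low signal in DC, and Slc27a3 and Dpp4 in P4. Itgam differed by 0.24 (adjusted p = 0.58).

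Of 32 macrophage core genes 24 rose in macrophages and 0 fell (25 and 0 adjusted over the list alone, adjusted p = 1.1e-32). Of 25 tissue-resident macrophage genes 20 rose and 0 fell (20 and 1 adjusted over the list alone, adjusted p = 5.7e-39). Conventional DC core genes gave 14 falls among 24 (14 adjusted over the list alone, adjusted p = 2.8e-15). MHC class II genes gave 9 among 10 (9 adjusted over the list alone, adjusted p = 4.1e-16), with a list mean of 8.55 in P4, 9.99 in P5 and 10.52 in DC, and cell cycle genes 19 among 25 (21 adjusted over the list alone, adjusted p = 1.9e-15). Complement genes rose in 8 of 12 cases (10 adjusted over the list alone, adjusted p = 2.8e-14), scavenger receptors in 10 of 16 with 1 fall (10 and 1 adjusted over the list alone, adjusted p = 6.6e-13). Lysosome genes rose in 11 of 18 with 1 fall (11 and 2 adjusted over the list alone, adjusted p = 2e-11) and interferon response genes in 9 of 23 (12 adjusted over the list alone, adjusted p = 1.6e-08). The NK cell list fell, with Klrd1 24.2-fold and Klrk1 21.5-fold lower and 2 falls among 10 (2 adjusted over the list alone, adjusted p = 0.002), both genes having low signal in P4. The plasmacytoid DC list had 2 rises among 7 (3 adjusted over the list alone, adjusted p = 0.049, and adjusted p = 0.095 with an estimated correlation). That call also ended with the replicate block (0.051), quantile normalization (0.057), low values left out (0.091), and without replicate 2 or 3 of P4, 3 of P5 or 1 or 2 of DC (0.052 to 0.15). Fibroblast genes gave 4 rises among 12 (4 adjusted over the list alone, adjusted p = 0.0012, and adjusted p = 0.42 with an estimated correlation) and keratinocyte genes 0 among 14 (4 adjusted over the list alone, adjusted p = 0.0031, and adjusted p = 0.47 with an estimated correlation). The B cell, T cell, erythroid and platelet, and neutrophil lists did not pass (adjusted p from 0.34 to 0.91). Mast cell and basophil genes gave 0 calls among 10 (adjusted p = 0.0076, adjusted p = 0.34 with an estimated correlation, and 0.078 without replicate 3 of P4). Of 19937 genes 944 rose and 1015 fell.

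Beside P3, macrophages as the mean of P4 and P5 held more RNA of tissue-resident macrophage genes and less of monocyte genes. Ccl8 was 48.6-fold higher (5.60, SE 1.04), Cd209f 21.7-fold (4.44, SE 0.41) and Lyve1 19.5-fold (4.29, SE 0.44), at 10.32 in P4 and 9.01 in P5 against 5.38. Enpep rose 12.6-fold (3.66, SE 0.17), and Folr2, Ednrb, C4b and Stab1 rose by 4.00, 3.87, 3.54 and 2.67. Gpr141 was 11.4-fold lower (-3.51, SE 0.33), the fibronectin gene Fn1 8.05-fold (-3.01, SE 0.30) and Ccr2 4.07-fold (-2.03, SE 0.24). Cd226, Klrb1b, Itgax, Il1b, Clec4e and H2-Eb1 fell by 3.30, 3.46, 2.53, 1.79, 1.97 and 1.80. Fcgr1 differed by -0.09 (adjusted p = 0.97) and Itgam by -0.09 (adjusted p = 0.95). Tissue-resident macrophage genes gave 12 rises among 25 (14 adjusted over the list alone, adjusted p = 9.4e-23) and MHC class II genes 6 falls among 10 (6 adjusted over the list alone, adjusted p = 1.6e-15). The MHC class II list mean was 8.55 in P4, 9.99 in P5 and 10.07 in P3, so that the fall of the pooled macrophages came from P4, sorted as MHC II negative. Enpep had low signal in P3, and Gpr141 and Cd226 in P4. NF-kB targets gave 6 falls among 15 (7, and 1 rise, adjusted over the list alone, adjusted p = 1.2e-07), classical monocyte genes 4 falls among 10 (5 adjusted over the list alone, adjusted p = 7.4e-06). Alternative activation genes gave 1 rise and 5 falls among 16 (2 and 7 adjusted over the list alone, adjusted p = 0.00011), at 7.05 in P4, 7.97 in P5 and 8.19 in P3. The plasmacytoid DC list had 3 rises among 7, Siglech by 2.49 (SE 0.41), and Cox6a2 by 1.15 among them (3 adjusted over the list alone, adjusted p = 0.00014). The 339 rises and 381 falls, 720 genes, became 352 when only these groups were fitted and 454 without replicate 2 of P3.

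MHC II+ P5 macrophages differed from MHC II-negative P4 macrophages by higher RNA of MHC class II genes and of the chemokine genes Ccl17 and Ccl22. Ccl17 was 62.4-fold higher in P5 (5.96, SE 0.30, adjusted p = 5.7e-14), at 10.90 (SD 0.04) against 4.94 (SD 0.88). Ccl22, which attracts T cells through the same receptor, rose 13.7-fold (3.78, SE 0.35), and the elastase gene Mmp12 12.4-fold (3.63, SE 0.33). H2-Eb1 rose 9.6-fold (3.26, SE 0.13), H2-Ab1 4.64-fold (2.21, SE 0.15), and H2-Aa and Cd74 by 2.28 and 1.31. Cxcl9, induced by interferon gamma, rose by 2.85 (SE 0.55), a call lost without replicate 2 of P4 or 1 of P5 (adjusted p = 0.077 and 0.064). Klrb1b rose by 2.92, P2ry10 by 2.83, Ccr7 by 2.39 (SE 0.27), Flt3 by 2.06 (SE 0.33), Itgax by 1.90 (SE 0.20) and Il1b by 1.88 (SE 0.31). The iron exporter gene Slc40a1 was 6.93-fold lower (-2.79, SE 0.34). Sema6a, Cmah, Cpne8 and Enpep fell by 2.29, 2.12, 2.05 and 1.93. Ccr2 differed by 1.01 (SE 0.27, adjusted p = 0.11, and 0.04 without replicate 2 of P4), Fcgr1 by 0.40 (adjusted p = 0.92) and Itgam by 0.18 (adjusted p = 0.96). Of 10 MHC class II genes 6 rose (8 adjusted over the list alone, adjusted p = 4.2e-38), and of 24 conventional DC core genes 3 rose (8 adjusted over the list alone, adjusted p = 1.2e-09). Of 25 DC maturation genes 3 rose (6 adjusted over the list alone, adjusted p = 6.7e-08) and of 16 alternative activation genes 2 (5 adjusted over the list alone, adjusted p = 2.9e-08). The CD11b+ DC list had 1 rise among 13 (adjusted p = 0.03, and adjusted p = 0.23 with an estimated correlation). Its direction turned without the members on another list (adjusted p = 0.956), the call also ending without replicate 2 of P4 (0.058) or 1 of P5 (0.19). The count of 58 rises and 40 falls, 98 genes, was 19 when only P4 and P5 were fitted, the rising share going from 59.2% to 84.2%. That fit ended the calls of Ccl22 (adjusted p = 0.083), Cd74, Flt3 and Slc40a1 (0.071 each), Cpne8 (0.13), Enpep (0.3), Klrb1b (0.15), Sema6a (0.23) and Cxcl9 (0.51). Slc40a1 had low signal in P5 and P2ry10 in P4.

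**Figure D3:**
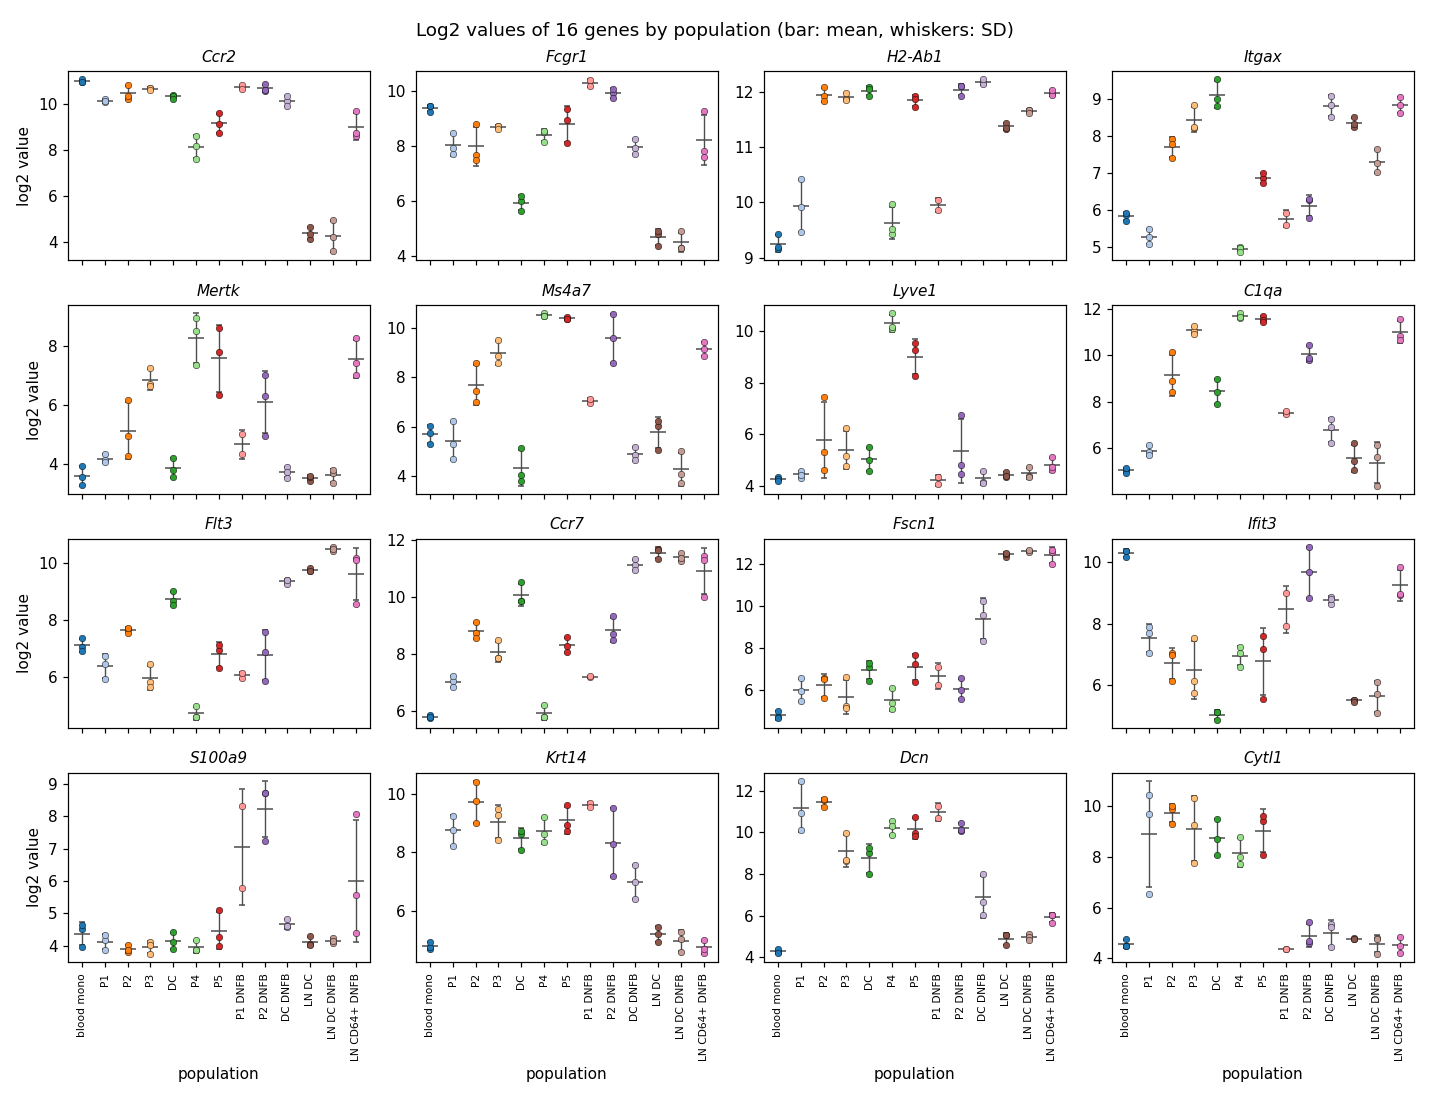
Log2 values of 16 genes in each of 38 arrays, 1 point per array, by population on the x axis, with the bar at the group mean and the whiskers at 1 SD. P5 macrophages lie above P4 for H2-Ab1 and Itgax, Ms4a7 is lower in DC than in P3 and macrophages, Fscn1 is highest in lymph node cells, and Cytl1 is lower after DNFB in P1, P2 and DC.

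After DNFB, P1 cells gained RNA of Saa3, of Fcgr1 and of interferon-induced genes. Saa3, an acute phase gene, was 20.7-fold higher (4.37, SE 0.41), at 7.76 (SD 0.05) against 3.39 (SD 0.35). Ifitm1 rose 10.8-fold (3.44, SE 0.46), Fcgr1 4.78-fold (2.26, SE 0.38), Arg1, which breaks down arginine, 4.54-fold (2.18, SE 0.23, adjusted p = 1.8e-06), and the platelet chemokine gene Ppbp 24-fold (4.59, SE 0.79). The calprotectin gene S100a9 rose by 2.92 (SE 0.63), from 4.13 (SD 0.24) to 7.05 (SD 1.79). Cxcl3 rose by 2.73 (SE 0.42), Timp1 by 3.18 (SE 0.70), Vcan by 1.72 (SE 0.35) and the interleukin-4 receptor gene Il4ra by 1.05. The antiviral genes Rsad2, Oas1a and Usp18 rose by 1.92, 1.68 and 1.61. Col8a1, a collagen gene, fell by 3.43 (SE 0.41). Cytl1 was 23.1-fold lower (-4.53, SE 0.71), Chad, made by chondrocytes, 23.6-fold (-4.56, SE 0.74) and Fmod fell by 2.95 (SE 0.64). H2-Ab1 differed by 0.02 (adjusted p = 0.99), Ccr2 by 0.59 (adjusted p = 0.52) and Itgam by 0.64 (adjusted p = 0.31). Of 23 interferon response genes 3 rose (13 adjusted over the list alone, adjusted p = 2.2e-15), and of 24 inflammatory mediators 4 rose (8 adjusted over the list alone, adjusted p = 2.2e-09). Of 14 glycolysis genes 1 rose, Ldha by 0.80 (4 adjusted over the list alone, adjusted p = 2.6e-06), and of 16 alternative activation genes 3 (4 adjusted over the list alone, adjusted p = 0.0077, and 0.061 without replicate 3 of steady-state P1). The neutrophil list did not pass, with 1 rise among 11 (adjusted p = 0.38), but replicate 2 after DNFB stood at 5.14 and replicate 1 at 4.57, beside 4.48 (SD 0.06) at steady state. Among erythroid and platelet genes 1 of 7 rose (adjusted p = 0.63, the median, mean and test differing in sign). With n = 2 after DNFB, 112 genes rose and 15 fell. This count of 127 was 274 with the keratinocyte and fibroblast covariates, and 1, Saa3, when only P1 arrays were fitted. It was 31 without replicate 1 of P1 after DNFB, and 201 and 83 without replicates 1 and 3 of steady-state P1. The rising share of 88.2% was 61.3% with the covariates, and 61.7% and 67.5% without replicates 1 and 3 of steady-state P1. Without replicate 1 of P1 after DNFB the calls of Fcgr1 (adjusted p = 0.076), Chad (0.051), Rsad2 (0.14), Usp18, Vcan, Il4ra, Timp1, Fmod and Ldha ended. Without replicate 2 those of S100a9 (0.47), Ppbp (0.055), Usp18, Vcan, Timp1, Fmod and Ldha ended. Ldha, Timp1, Vcan, Fmod and S100a9 also lost theirs without 1 of the steady-state arrays (0.053 to 0.13). Array weights ended those of S100a9 (0.11) and Ldha (0.057), and centring of array medians that of Ldha (0.064). Saa3 had low signal at steady state and Chad after DNFB, with Cytl1 after DNFB at 4.36 beside 4.57 in blood.

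In P2 the DNFB response joined a rise of interferon-induced genes with lower RNA of Ccl17, Retnla and Mgl2. Ifitm1 rose 12.1-fold (3.60, SE 0.41), and S100a9 20-fold (4.32, SE 0.56), from 3.90 (SD 0.12) to 8.23 (SD 0.86). Fcgr4, an activating IgG receptor gene, rose 11.9-fold (3.58, SE 0.46), and Fcgr1 3.85-fold (1.95, SE 0.34). The interferon-induced genes Slfn4, Ifi213, Ifit2, Oas1a, Mx1, Oas2 and Zbp1 rose by 3.22, 3.18, 2.37, 2.22, 2.12, 2.07 and 1.79. Saa3 rose by 2.90 (SE 0.37), Stat4 by 2.30 (SE 0.36), Vcan by 1.71 and Ccr1 by 1.83. Ccl17 was 19.9-fold lower (-4.31, SE 0.30), at 6.12 (SD 0.22) against 10.43 (SD 0.57). Retnla was 12.8-fold lower (-3.68, SE 0.45), Mgl2 5.12-fold (-2.36, SE 0.35) and Itgax 3-fold (-1.58, SE 0.20). Ccl22, Irf4 and Top2a fell by 1.83, 1.65 and 1.36. Cytl1 was 28.4-fold lower (-4.83, SE 0.63) and Chad 25.8-fold (-4.69, SE 0.66). Timp3 and Col8a1 fell by 4.12 and 3.48. H2-Ab1 differed by 0.09 (adjusted p = 0.89), Ccr2 by 0.21 (adjusted p = 0.86) and Itgam by 0.76 (adjusted p = 0.071). Of 23 interferon response genes 11 rose and 1 fell (17 and 1 adjusted over the list alone, adjusted p = 8.6e-21). Of 16 alternative activation genes 3 rose and 7 fell (3 and 9 adjusted over the list alone, adjusted p = 3.2e-08, and 0.83 without the members on another list). Cell cycle genes gave 4 falls among 25 (7 adjusted over the list alone, adjusted p = 1.6e-10) and CD11b+ DC genes 3 among 13 (3, and 1 rise, adjusted over the list alone, adjusted p = 0.0002, and 0.25 without the members on another list). The neutrophil list, with S100a9, rose from 4.12 (SD 0.10) to 4.88 (SD 0.30). It had 1 rise and 1 fall among 11 (3 and 1 adjusted over the list alone, adjusted p = 0.013). The call ended with an estimated correlation (0.15), without replicate 3 after DNFB (0.23) or the members on another list (0.052). The CD11b gate keeps neutrophils, but P2 was also CD64+ and MHC II+. The keratinocyte list fell, in replicates 2 and 3 after DNFB (6.23 and 5.86) but not in replicate 1 (7.59, against 7.48 to 8.16 at steady state), with Krt15 down by 2.05 (SE 0.39) and 3 falls among 14 (10 adjusted over the list alone, adjusted p = 9.3e-14). So did the fibroblast list, with 1 fall among 12 (6 adjusted over the list alone, adjusted p = 9e-09, and adjusted p = 0.12 with an estimated correlation). The 203 rises and 199 falls, 402 genes, became 153 with those lists as covariates, 80 when only P2 was fitted, and 241 and 251 without replicates 2 and 3 of P2 after DNFB. The rising share of 50.5% was 28.8% when only P2 was fitted and 38.6% without replicate 3 of steady-state P2. With the covariates the calls of Fcgr1 (1.51, adjusted p = 0.096), Vcan (1.31), Ccr1 (1.17), Timp3 (-2.28) and Krt15 (-1.01) ended, and that of Ccl22 at nearly the same size (-1.73, adjusted p = 0.06). When only P2 was fitted, those of Retnla (adjusted p = 0.051), Saa3 (0.087), Mx1 (0.089), Irf4 (0.11), Top2a (0.068), Fcgr1 (0.095), Ccl22 (0.094), Vcan, Ccr1 and Krt15 ended. S100a9, Saa3 and Ifit2 had low signal at steady state.

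Dermal DC answered DNFB with a gain of interferon-induced genes and a loss of RNA of tissue-resident macrophage genes. Ifitm1 was 37.1-fold higher (5.21, SE 0.41), at 12.25 (SD 0.10) against 7.04 (SD 0.16). Tnfsf4, which encodes the T cell costimulator OX40L, rose 24.1-fold (4.59, SE 0.42), to 9.67 (SD 0.29) from 5.08 (SD 1.23). Plac8 rose 27.4-fold (4.78, SE 0.62), Cd72 23.9-fold (4.58, SE 0.41) and the fatty acid receptor gene Ffar2 16.5-fold (4.05, SE 0.19). Stat4 rose 13.1-fold (3.72, SE 0.36) and the stem cell factor receptor gene Kit 10.6-fold (3.40, SE 0.23). Oasl2 rose 12.1-fold (3.60, SE 0.30), Ifit3 13.1-fold (3.72, SE 0.44), Irf7 by 3.13 and Oas1a by 2.66. Fscn1, an actin bundler of mature DC, rose by 2.45 (SE 0.42), Cd274 by 1.45 and Ccr7 by 1.05 (SE 0.27), the last lost without replicate 1 or 3 of steady-state DC or 1 or 2 of DC after DNFB (adjusted p from 0.056 to 0.11). Fcgr1 rose 4.1-fold (2.04, SE 0.34), from 5.94 (SD 0.28) to 7.98 (SD 0.28), although the cells were sorted as CD64-negative. Cd163 was 10.6-fold lower (-3.40, SE 0.34), Hepacam2 9.46-fold (-3.24, SE 0.15) and Cytl1 13.5-fold (-3.76, SE 0.63). C1qc, Igf1, Ccl2, Apoe, Ccl17 and Mki67 fell by 2.72, 2.66, 1.93, 1.34, 1.47 and 1.26. H2-Ab1 differed by 0.16 (adjusted p = 0.78), Itgax by -0.30 (adjusted p = 0.59), Itgam by 0.48 (adjusted p = 0.31) and Ccr2 by -0.20 (adjusted p = 0.88).

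Of 23 interferon response genes 11 rose in DC after DNFB and 0 fell (17 and 1 adjusted over the list alone, adjusted p = 3.6e-20). Of 25 tissue-resident macrophage genes 12 fell (17 adjusted over the list alone, adjusted p = 3.6e-18). Cell cycle genes gave 7 falls among 25 (13 adjusted over the list alone, adjusted p = 5.9e-10). Alternative activation genes gave 2 rises and 5 falls among 16 (2 and 9 adjusted over the list alone, adjusted p = 3e-05, and 0.26 without the members on another list) and chemokine receptors 3 rises among 15 (5 adjusted over the list alone, adjusted p = 0.001). DC maturation genes gave 7 rises among 25 (7 adjusted over the list alone, adjusted p = 2.6e-06, and adjusted p = 0.082 with an estimated correlation). The NK cell list rose from 4.55 (SD 0.08) to 4.98 (SD 0.12), with 2 rises among 10 (4, and 1 fall, adjusted over the list alone, adjusted p = 0.0039, and adjusted p = 0.062 with an estimated correlation). Classical monocyte genes gave 3 rises and 1 fall among 10 (4 and 2 adjusted over the list alone, adjusted p = 0.19, and 0.025 without the members on another list). Krt15 fell by 1.81 (adjusted p = 0.075 with the keratinocyte and fibroblast covariates), with 2 of 14 keratinocyte genes falling (8 adjusted over the list alone, adjusted p = 2e-06, and adjusted p = 0.21 with an estimated correlation). Altogether 420 genes rose and 410 fell, a rising share of 50.6% that was 35.5% with array medians centred. The total of 830 was 1373 with array weights and 506 without replicate 1 of DC after DNFB.

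The DNFB effects in DC and in P2 were compared by their difference. Kit separated them by 3.26 (SE 0.33), going from 4.14 to 7.54 in DC and from 4.39 to 4.53 in P2. Ffar2 separated them by 3.02 (SE 0.26), Tnfsf4 by 3.02 (SE 0.60), the semaphorin gene Sema7a by 2.93, Cyp7b1 by 3.91 (SE 0.41) and Prnp by 3.44. Ccl17 fell less in DC (2.85, SE 0.43), from 12.24 to 10.77, than in P2, from 10.43 to 6.12. S100a9 separated them the other way (-3.81, SE 0.79), at 4.15 and 4.67 in DC and 3.90 and 8.23 in P2. So did C1qc (-3.00, SE 0.60), going from 10.20 to 7.49 in DC against a difference of 0.29 in P2 (adjusted p = 0.877), Pf4 (-3.36, SE 0.65) and Apoe (-1.56, SE 0.31). Fcgr1 differed by 0.09 between the effects (adjusted p = 1). Of 25 tissue-resident macrophage genes 4 had the lower effect in DC (14, and 1 higher, adjusted over the list alone, adjusted p = 1.2e-16), and of 24 inflammatory mediators 1 (9 adjusted over the list alone, adjusted p = 1.5e-09). Of 13 CD11b+ DC genes 2 had the higher effect in DC (3 adjusted over the list alone, adjusted p = 4.5e-07). DC maturation genes gave 0 calls among 25 at the gene level (9 higher adjusted over the list alone, adjusted p = 4.5e-09). In all 50 genes passed, 26 higher and 24 lower in DC, 52% and 40% higher without and with centred medians. The count was 22 when only these groups were fitted, 83 with array weights, 24 without replicate 1 of DC after DNFB and 29 without replicate 2 of P2 after DNFB. It was 33 and 32 without replicates 2 and 3 of steady-state P2 and 32 without replicate 3 of steady-state DC. The calls of Tnfsf4, Prnp, S100a9, C1qc, Pf4 and Apoe each ended without replicate 1 of DC after DNFB (adjusted p from 0.062 to 0.12) and without replicate 2 of P2 after DNFB (0.061 to 0.1), and each without at least 1 further array. When only these groups were fitted, those of Tnfsf4 (0.24), C1qc (0.12), Pf4 (0.11) and Apoe (0.18) ended. Prnp also lost its call with the replicate block (0.0502), centring of array medians (0.076), all probe sets (0.073) and the covariates (0.082), and S100a9 with array weights (0.1) and the covariates (0.059).

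Migratory DC of the lymph node at steady state held more RNA of DC maturation genes than dermal DC and less of mediators and of tissue-resident macrophage genes. Fscn1 was 46.2-fold higher in the node (5.53, SE 0.42), at 12.46 against 6.93. Apol7c rose 123-fold (6.95, SE 0.33), to 11.73 (SD 0.02) from 4.79 (SD 0.67). Serpinb6b rose 78.4-fold, Il2ra, the gene of CD25, 44-fold (5.46, SE 0.31), and Anxa3 and H2-M2 rose by 5.72 and 5.31. Ccr7 rose 2.78-fold (1.48, SE 0.27), Relb and Nfkb2 by 2.33 and 1.49. Gbp5 rose by 4.30 (SE 0.25), and the sterol synthesis genes Idi1, Hmgcs1 and Mvd by 3.37, 1.82 and 1.80. Mgl2 was 281-fold lower (-8.13, SE 0.35), the decoy receptor gene Il1r2 101-fold (-6.66, SE 0.24), Mrc1 98.8-fold (-6.63, SE 0.31) and Cd14, a coreceptor for endotoxin, 94.5-fold (-6.56, SE 0.26). Ccl2 was 67.9-fold lower (-6.09, SE 0.33), Ccr2 61.8-fold (-5.95, SE 0.27), Nr4a1 47.1-fold (-5.56, SE 0.24), Il1b 33.3-fold (-5.06, SE 0.31) and Mki67 10.3-fold (-3.37, SE 0.25). Itgam, the gene of the CD11b sort marker, was 29.7-fold lower (-4.89, SE 0.22), at 4.62 (SD 0.11) against 9.52 (SD 0.17). H2-Ab1 fell by 0.64 (SE 0.15, adjusted p = 0.0016). Il2ra had low signal in dermal DC, and Mgl2, Il1r2 and Mrc1 in the node.

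Of 25 DC maturation genes 20 rose in the node and 3 fell (20 and 3 adjusted over the list alone, adjusted p = 6.6e-15). Inflammatory mediators gave 15 falls among 24 (16 adjusted over the list alone, adjusted p = 5e-15), cell cycle genes 16 among 25 (19 adjusted over the list alone, adjusted p = 1.5e-13). Tissue-resident macrophage genes gave 16 falls and 1 rise among 25 (17 and 1 adjusted over the list alone, adjusted p = 1e-16) and alternative activation genes 8 falls and 2 rises among 16 (9 and 2 adjusted over the list alone, adjusted p = 1.3e-07). Conventional DC core genes gave 11 rises and 4 falls among 24 (12 and 6 adjusted over the list alone, adjusted p = 0.036, and adjusted p = 0.41 with an estimated correlation). That call also ended without replicate 3 of steady-state dermal DC (0.087) and without the members on another list (0.066). CD11b+ DC genes gave 2 rises and 6 falls among 13 (2 and 6 adjusted over the list alone, adjusted p = 0.00036). Cholesterol synthesis genes rose in 9 of 16 cases (12 adjusted over the list alone, adjusted p = 1.1e-05, and adjusted p = 0.061 with an estimated correlation). Immediate early genes gave 10 falls and 2 rises among 20 (10 and 2 adjusted over the list alone, adjusted p = 8.9e-07, and adjusted p = 0.055 with an estimated correlation). Krt5 was 19.9-fold lower in the node (-4.31, SE 0.40), and 11 of 14 keratinocyte genes fell (12 adjusted over the list alone, adjusted p = 1.2e-08, and adjusted p = 0.12 with an estimated correlation). Of 4040 genes 2023 rose and 2017 fell, with a rising share of 50.1% that was 37.6% after centring of array medians. Organ and digestion enzyme differ together with the migration state.

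After DNFB the lymph node and dermal DC were again far apart. Apol7c was 142-fold higher in the node (7.15, SE 0.33), H2-M2 62.6-fold (5.97, SE 0.24) and the clusterin gene Clu 37.5-fold (5.23, SE 0.37). Il15, a growth factor gene for T and NK cells, rose 30.7-fold (4.94, SE 0.56). Cd40, Batf3, Relb, Idi1, Fdft1 and Gbp5 rose by 2.13, 2.65, 2.31, 2.82, 2.44 and 4.72. Il1r2 was 132-fold lower (-7.05, SE 0.24), Cd209a 105-fold, Cd14 89-fold and Ifitm6 84.5-fold (-6.40, SE 0.52). Ccr2 was 59.6-fold lower (-5.90, SE 0.27), Nr4a1 56.1-fold (-5.81, SE 0.24), Itgam 38.3-fold (-5.26, SE 0.22) and Fcgr1 11.2-fold (-3.48, SE 0.34). Plac8, Ifit3, Il1b and Pfkp fell by 4.80, 3.13, 3.72 and 2.53. H2-Ab1 differed by -0.52 (adjusted p = 0.012). Of 25 DC maturation genes 20 rose and 1 fell (20 and 2 adjusted over the list alone, adjusted p = 5.4e-16), and of 21 pattern recognition receptors 0 rose and 11 fell (1 and 11 adjusted over the list alone, adjusted p = 1.2e-10). Of 24 inflammatory mediators 0 rose and 12 fell (1 and 15 adjusted over the list alone, adjusted p = 7.7e-10), and of 10 classical monocyte genes 6 fell (6 adjusted over the list alone, adjusted p = 8.8e-09). Of 14 glycolysis genes 1 rose and 7 fell (1 and 8 adjusted over the list alone, adjusted p = 7.7e-06). The interferon response list was divided, with 4 rises and 9 falls among 23 (4 and 9 adjusted over the list alone, adjusted p = 0.14). The cDC1 and Langerhans cell list had 2 rises and 4 falls among 12 (2 and 5 adjusted over the list alone, adjusted p = 0.028, adjusted p = 0.086 with an estimated correlation, and 0.093 with low values left out). Krt5 was 9.97-fold lower (-3.32, SE 0.40). A total of 1683 genes rose and 1803 fell, and the sum of 3486 was 5705 with array weights. Organ and digestion enzyme differ here too. Cd14 and Ifitm6 had low signal in the node.

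Within the lymph node, DNFB raised the costimulator genes Cd80 and Cd86 and genes of antigen presentation in migratory DC. Cd86 rose 4.51-fold (2.17, SE 0.26), Cd80 4.76-fold (2.25, SE 0.28), Ciita, the master regulator of MHC class II genes, 4.03-fold (2.01, SE 0.27) and H2-DMa by 1.35 (SE 0.19). The Notch ligand gene Dll4 rose 12.3-fold (3.62, SE 0.28), from 4.94 (SD 0.09) to 8.57 (SD 0.35), and Atp1b1 rose 11.7-fold (3.55, SE 0.28) and Ifitm1 11.6-fold (3.53, SE 0.41). The interferon-induced chemokine genes Cxcl9 and Cxcl10 rose by 2.98 (SE 0.55) and 2.72 (SE 0.46). Mmp14 rose by 2.79 (SE 0.38), Cd200 by 1.81, Cd274 by 1.43, Il1b by 1.67 (SE 0.31) and Oasl2 by 1.64. Aldh1a2, which makes retinoic acid, was 4.02-fold lower (-2.01, SE 0.33). Retnla fell by 2.43 (SE 0.45, adjusted p = 0.063 when only these groups were fitted), Adgre1, the gene of F4/80, by 1.89 (SE 0.26), Ets2 by 1.85 (SE 0.22) and Itgax by 1.04 (SE 0.20). H2-Ab1 differed by 0.28 (adjusted p = 0.66). Of 10 MHC class II presentation genes 2 rose (2 adjusted over the list alone, adjusted p = 1.1e-06). Of 23 interferon response genes 4 rose (6, and 1 fall, adjusted over the list alone, adjusted p = 4.4e-07). DC maturation genes gave 4 rises and 1 fall among 25 (5 and 1 adjusted over the list alone, adjusted p = 0.002, adjusted p = 0.27 with an estimated correlation, and 0.076 without replicate 3 after DNFB). Lysosome genes gave 3 falls among 18 (4, and 1 rise, adjusted over the list alone, adjusted p = 0.0034, adjusted p = 0.4 with an estimated correlation, and 0.17 without replicate 2 after DNFB). In all 180 genes rose and 88 fell, and the sum of 268 was 765 with array weights and 162 without replicate 1 of lymph node DC after DNFB.

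The DNFB effect in lymph node DC differed from that in dermal DC for Cxcl9 (4.45, SE 0.78), which went from 6.75 to 9.73 in the node and from 8.81 to 7.34 in the dermis. Cd86 (2.03, SE 0.37) went from 8.45 to 10.62 in the node and from 10.15 to 10.29 in the dermis. Dll4 (3.24, SE 0.40), Atp1b1 (3.39, SE 0.40), Cd302 (3.42, SE 0.43), and Irf4 (2.20) also had the higher effect in the node. Tnfsf4 was raised more in the dermis (-4.44, SE 0.60), as were Plac8 (-4.28, SE 0.88), Cd72 (-4.02, SE 0.58), Ifitm6 (-4.16), Il21r (-3.55), Stat4 (-2.85), Kit (-2.82), Oas1a (-2.29) and Fcgr1 (-2.23, SE 0.48, adjusted p = 0.056 with the keratinocyte and fibroblast covariates). Ifit3 (-3.59, SE 0.63) went from 5.06 to 8.77 in the dermis and from 5.52 to 5.65 in the node. Of 23 interferon response genes 2 had the higher and 7 the lower effect in the node (2 and 10 adjusted over the list alone, adjusted p = 3.5e-07), and of 25 cell cycle genes 4 the higher (8 adjusted over the list alone, adjusted p = 2.1e-10). Of 16 alternative activation genes 4 had the higher effect (6, and 1 lower, adjusted over the list alone, adjusted p = 5e-06), of 24 inflammatory mediators 2 the higher (9 adjusted over the list alone, adjusted p = 2.6e-06). Of 10 NK cell genes 2 had the lower effect (3 adjusted over the list alone, adjusted p = 0.00095). In total 162 genes had the higher and 99 the lower effect in the node, a share of 62.1% higher that was 73.1% with centred medians. The sum of 261 was 419 when only these groups were fitted, 771 with array weights and 170 without replicate 1 of dermal DC after DNFB.

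CD64+ migratory cells, which the labels call a non-DC in the title, a migratory monocyte in the cell type and a DC in the description, carried a macrophage programme beside lymph node DC after DNFB. C1qc was 68.7-fold higher in CD64+ cells (6.10, SE 0.42), at 11.48 (SD 0.26) against 5.38 (SD 0.64). C1qb rose 66.5-fold, C1qa 50.4-fold (5.66, SE 0.38) and Pf4 54.4-fold (5.77, SE 0.46). The complement receptor gene C3ar1 rose 43.5-fold (5.44, SE 0.31) and the lipid carrier gene Apoe 16.7-fold (4.06, SE 0.22). Ccr2 rose 27.6-fold (4.79, SE 0.27), Itgam 15-fold (3.91, SE 0.22), Fcgr1 13.3-fold (3.74, SE 0.34) and Itgax by 1.53 (SE 0.20). Msr1, Selenop, Mrc1, Cx3cr1, Plac8, Irf7, Ccl2, Ifit2 and Cd68 rose by 5.01, 5.05, 4.65, 4.21, 3.98, 3.84, 3.65, 3.14 and 2.40. Khdc1a was 7.25-fold lower (-2.86, SE 0.32). Dkk2, Cdh2, Atp1b1 and Dscam fell by 2.00, 1.92, 1.78 and 1.74, the last with adjusted p = 0.069 when only these groups were fitted. C3ar1 and Msr1 had low signal in lymph node DC. H2-Ab1 differed by 0.32 (adjusted p = 0.29) and Cd24a by -1.43 (adjusted p = 0.1). Of 32 macrophage core genes 25 rose and 0 fell (27 and 0 adjusted over the list alone, adjusted p = 4.6e-51), and of 25 tissue-resident macrophage genes 17 rose and 0 fell (18 adjusted over the list alone, adjusted p = 2.4e-39). Of 21 pattern recognition receptors 16 rose (18 adjusted over the list alone, adjusted p = 2.4e-32), and of 18 lysosome genes 13 (14 adjusted over the list alone, adjusted p = 1.5e-26), each with 0 falls. Of 16 scavenger receptors 11 rose (11 adjusted over the list alone, adjusted p = 1.3e-25), of 12 complement genes 7 (8 adjusted over the list alone, adjusted p = 5.4e-24) and of 23 interferon response genes 12 (14 adjusted over the list alone, adjusted p = 1.5e-19), each with 0 falls. DC maturation genes gave 0 rises and 1 fall among 25 (0 and 1 adjusted over the list alone, adjusted p = 0.0077, and adjusted p = 0.36 with an estimated correlation), a direction that turned without replicate 3 of the CD64+ cells (adjusted p = 0.976), the call also ending without replicate 3 of lymph node DC (0.13). Alternative activation genes gave 5 rises among 16 (6, and 2 falls, adjusted over the list alone, adjusted p = 0.00048), turning without the members on another list (adjusted p = 0.783). The 761 rises and 200 falls, 961 genes, became 3259 with array weights, the rising share going from 79.2% to 41.8%, so that falls outnumbered rises. They became 534 without replicate 3 of the CD64+ cells.

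Beside dermal P2 cells after DNFB, the CD64+ lymph node cells carried the genes of mature migratory DC. Apol7c was 270-fold higher (8.08, SE 0.33), at 11.12 (SD 0.57) against 3.05 (SD 0.21). Serpinb6b rose 107-fold (6.74, SE 0.38), Fscn1 84.8-fold (6.41, SE 0.42) and the nuclease gene Dnase1l3 82.5-fold (6.37, SE 0.29). Il2ra rose 56.2-fold, Ccl17 54.9-fold (5.78, SE 0.30), Ccl22 45-fold and Ccr7 4.25-fold (2.09, SE 0.27). Flt3, Irf8, Itgax, Cxcl9, Gbp5 and Idi1 rose by 2.84, 2.41, 2.72, 5.20, 4.35 and 3.45. The thrombospondin gene Thbs1 was 115-fold lower (-6.84, SE 0.29), the lectin gene Clec4e 53.7-fold (-5.75, SE 0.28), Il10 50.7-fold (-5.66, SE 0.34) and Vcan 34.6-fold. Trem1, Cd14, Hp, Cxcl2, Il1b and Nr4a1 fell by 5.51, 4.70, 4.22, 4.81, 2.94 and 4.70. Fcgr1 was 3.26-fold lower (-1.70, SE 0.34), Ccr2 3.16-fold (-1.66, SE 0.27) and Itgam fell by 1.87 (SE 0.22). H2-Ab1 differed by -0.06 (adjusted p = 0.9). Of 25 DC maturation genes 19 rose and 0 fell (21 and 1 adjusted over the list alone, adjusted p = 1.5e-30), and of 24 conventional DC core genes 13 rose and 3 fell (13 and 3 adjusted over the list alone, adjusted p = 8.4e-07). Of 10 classical monocyte genes 8 fell (10 adjusted over the list alone, adjusted p = 2.3e-16) and of 24 inflammatory mediators 1 rose and 15 fell (2 and 15 adjusted over the list alone, adjusted p = 3.3e-11). Krt5 was 26.6-fold lower (-4.73, SE 0.40) and Dcn 19.8-fold (-4.31, SE 0.45). In the keratinocyte list 9 of 14 fell (13 adjusted over the list alone, adjusted p = 1.3e-10, and adjusted p = 0.076 with an estimated correlation). Together 1447 genes rose and 1070 fell, a sum of 2517 that was 1662 with the keratinocyte and fibroblast covariates. Immediate early and dissociation stress genes gave 1 rise and 8 falls among 20 (1 and 11 adjusted over the list alone, adjusted p = 1.1e-05, and adjusted p = 0.082 with an estimated correlation), and organ and digestion enzyme differ along with the cells. Replicate 3 of the CD64+ cells lay apart on component 1, at 31.6 beside 57.5 and 59.7, and the count without it was 2363. Apol7c and Il2ra had low signal in P2, and Trem1 in the CD64+ cells.

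**Figure D4:**
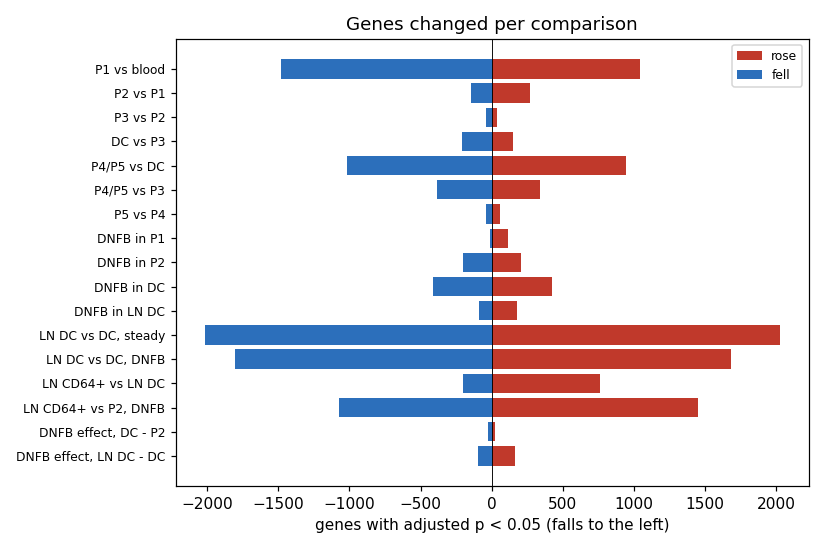
Genes that rose (bars to the right) and fell (bars to the left) at an adjusted p under 0.05 in each of 17 comparisons, in numbers of genes.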

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

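Tests chosen after the result was seen are the correlations of keratinocyte and fibroblast genes, the lower-quartile bound for P2-type RNA in DC and the splits with the common DNFB effect removed, while the other tests of this part had their bounds set before they were run.

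Krt5, Krt14, Dcn and Lum were higher in dermal P1 than in blood monocytes although the cells were sorted for CD11b, a gate that should remove keratinocytes and fibroblasts. Over 26 dermal arrays the deviations of the 14 keratinocyte genes from their group means correlated with a mean r of 0.605 (0.538 to 0.633 without 1 array, highest of 1000 random lists 0.148), so keratinocyte RNA carried over into the sorts is a candidate explanation. Those of the 12 fibroblast genes correlated with 0.671 (random lists 0.224), but with 0.272 without replicate 2 of steady-state P1. The fibroblast list mean was 9.70 in that array and 6.15 and 6.92 in the other P1 arrays at steady state, and the correlation leaves open whether fibroblast RNA was carried over. All dermal groups exceeded blood, from 1.40 (keratinocyte) and 0.59 (fibroblast) in DC after DNFB to 3.46 and 3.51 in steady-state P2, with Dcn at 11.18 (SD 1.18) in P1. Of the list members 11 of 14 and 9 of 12 lay above the low-value level in blood too, and 0 were on another list. Uptake of skin debris by the phagocytes may give the same pattern, and these arrays do not separate it from free RNA or from stray cells.

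Cytl1, Chad, Col8a1 and Fmod, genes of cartilage and matrix, changed after DNFB in P1, P2 and DC by a mean of -3.49 (SE 0.27). In DC, Fmod did not pass (-1.31, adjusted p = 0.277), and the call of Chad ended without replicate 1 or 2 of steady-state DC (adjusted p = 0.137 and 0.0628) or replicate 2 or 3 of DC after DNFB (0.0699 and 0.0681). In P1 the calls of Chad and Fmod ended without replicate 1 after DNFB. That of Fmod also ended without replicate 2 after DNFB or at steady state. Less RNA of ear cartilage cells, which the CD11b gate should remove, might explain this, but the other cartilage genes with a steady-state level of 5 or more, 5 of 20 in P1, 8 in P2 and 5 in DC, changed by a median of -0.25, -0.42 and -0.0859, which lies between the bounds set in advance and leaves the question open. Comp, Cnmd and Ucma fell in P2 (-1.46, SE 0.25, -1.26, SE 0.29, and -1.23, SE 0.32), the last 2 calls ending without 1 of several arrays (adjusted p up to 0.171 and 0.288). All 3 calls ended with keratinocyte and fibroblast covariates, Comp (-0.93, SE 0.28, adjusted p = 0.132) and Cnmd (-0.56, SE 0.32, adjusted p = 0.593) with a smaller change and Ucma (-1.29, SE 0.42, adjusted p = 0.192) with a wider error. With the same covariates the mean change of the first 4 genes was -3.19 (SE 0.29), so a fall of those cells' RNA does not explain the change of the 4 together, although Fmod in P2 did not pass with them (-1.72, adjusted p = 0.273). A shift of the cells themselves remains possible, and the source-name numbers differ along with DNFB.

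Fcgr1, Plac8 and Ifitm6 rose after DNFB in DC sorted as CD64-negative. P2-type cells might carry them in, although the CD64 gate should remove such cells. Fcgr1 would need 20.7% of P2 RNA, Plac8 50.3% and Ifitm6 123% (10.17, SD 0.24, in DC and 9.89, SD 0.4, in P2 after DNFB). The 48 other genes far higher in P2 allowed a median of 7.28% (quartiles 1.46% and 40.3%), which the bound set in advance left undecided. A second bound, chosen after this, asked whether P2-type cells can be the whole source. The lower quartile and 26 of 48 genes lay far below the share that Fcgr1 needs. Among them Dpt and S100a9 are fibroblast and neutrophil genes and say little here. Others, such as Msr1 (6.02 in DC, 6.03 after DNFB, 10.07 in P2 after DNFB), speak against P2-type cells alone. A partial share of such cells and a response of the DC remain possible side by side.

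The DNFB effect differed between dermal DC and P2 for 50 genes, a difference between groups, Kit (3.26, SE 0.33) among them, and between lymph node and dermal DC for 261 genes, Tnfsf4 (-4.44, SE 0.60) among them. Of 100 splits of the arrays 10 and 5 gave at least as many, the real one included, with up to 1403 and 781 genes. The other 9 and 4 all exchanged the labels of a whole cell type, which turns the difference of effects into their sum, so these counts do not decide about chance. In the same 100 splits with the common DNFB effect removed, only the real one gave as many for each (highest other 45 and 2). The removal used the real labels, which keeps the real count by construction and leaves chance undecided.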

How the results depend on the processing

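Tests chosen after the result was seen are the fits with the keratinocyte and fibroblast list means as covariates, and all other tests of this part were planned.

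No call of a named gene turned in an alternative run. Of 415 named-gene results 28 lost their call with the covariates and 65 with only the compared groups fitted. Leaving out 1 array ended 91 of 2790. Of 527 list tests, 246 passed as planned and 113 with an estimated correlation, a setting that allows for members moving together. Direction turned for the scavenger list of P2 against P1 (adjusted p = 0.126), the CD11b+ DC list of P5 against P4 (0.956) and the alternative activation list of CD64+ cells against lymph node DC (0.783), each without members on another list, and for the DC maturation list of CD64+ cells against lymph node DC without replicate 3 of the CD64+ cells (0.976, with a range from 9.82e-05 without replicate 1 of those cells). The cause was not tested.

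Counts of changed genes with the replicate block were within 1.5 times for all 17 comparisons (P1 against blood 2505 for 2520, DNFB in P1 107 for 127), and same-numbered arrays of different groups were not paired, with r from -0.26 to 0.35. The same held for the source-name number as a random block (consensus correlation 0.0033), quantile normalization, centring of array medians, low values left out (14841 genes), all probe sets or their mean, and the trend with robust variances.

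Centring left counts near but moved the rising share of P1 against blood from 41.2% to 29.1%, of DNFB in DC from 50.6% to 35.5%, of steady-state lymph node against dermal DC from 50.1% to 37.6%, and of the effect differences from 52% to 40% (DC and P2) and from 62.1% to 73.1% (lymph node and dermal DC). The large differences of Il6, Ifitm1 and Fscn1 passed with centring too.

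With the covariates P1 against blood had 292 genes, P3 against P2 205, DNFB in P1 274, DNFB in P2 153 and CD64+ cells against P2 1662, for 2520, 74, 127, 402 and 2517. The lists differ between these groups, so that the covariates remove part of the group difference itself, except for DNFB in P1 (keratinocyte 7.28 and 7.27, fibroblast 7.59 and 7.56), where the cause was not tested.

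Fitting only the compared groups, with fewer arrays to estimate variances, gave 1343 genes for P1 against blood, 62 for P2 against P1, 19 for P3 against P2, 101 for DC against P3, 352 for macrophages against P3, 19 for P5 against P4, 1 for DNFB in P1, 80 for DNFB in P2, 22 for the effects in DC and P2, and 419 for those in lymph node and dermal DC. Array weights (0.40 to 3.01) gave 124 for P3 against P2, 1373 for DNFB in DC, 765 for DNFB in lymph node DC, 5705 for lymph node against dermal DC after DNFB, 3259 for CD64+ cells against lymph node DC, and 83 and 771 for the effect differences. The cause was not tested.

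A change of at least 2-fold as well, a stricter rule by construction, left 1426 genes for P1 against blood, 969 for macrophages against DC, 376 for macrophages against P3, 81, 263, 490 and 166 for DNFB in P1, P2, DC and lymph node DC, 2331 and 2133 for lymph node against dermal DC at steady state and after DNFB, and 1551 for CD64+ cells against P2.

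Leaving out 1 array gave 56 to 167 genes for P3 against P2 (56 without replicate 2 and 167 without replicate 1 of P2), 454 to 692 for macrophages against P3 (454 without replicate 2 of P3), 31 to 201 for DNFB in P1 (31 without replicate 1 after DNFB, 201 and 83 without replicates 1 and 3 at steady state), 241 to 436 for DNFB in P2 (241 and 251 without replicates 2 and 3 after DNFB), 506 to 660 for DNFB in DC and 162 to 208 for DNFB in lymph node DC (506 and 162 without replicate 1 after DNFB), and 534 to 1032 for CD64+ cells against lymph node DC (534 without replicate 3 of the CD64+ cells). For the effects in DC and P2 it gave 24 to 72 (24 without replicate 1 of DC and 29 without replicate 2 of P2 after DNFB, 33 and 32 without replicates 2 and 3 of steady-state P2, 32 without replicate 3 of steady-state DC), and for those in lymph node and dermal DC 170 to 249 (170 without replicate 1 of dermal DC after DNFB). The other comparisons stayed within 1.5 times. Fewer arrays widen the error by construction, and the rest of the cause was not tested. Low signal limits the arrays, with 14841 of 19937 genes above the low-value level in at least 1 group.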

Other observations

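Tests of this part had their bound set before they were run.

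The splits below concern the macrophage counts, not single genes such as Ccl8, Ms4a7 and Lyve1. All comparisons except DNFB in P1 were repeated with the arrays regrouped. For macrophages against DC 1 of 84 splits, the real one, gave as many as 1959 genes (highest other 1042), and against P3 1 of 84 gave 720 (highest other 531), so chance does not explain these counts.

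For 12 comparisons of 3 against 3 arrays the real split was the 1 of 10 with the most genes, which is the smallest share these splits can give and cannot pass a bound of 5%. The highest other count was 1 for P1 against blood (2520), 218 for P2 against P1 (416), 4 for P3 against P2 (74), 2 for DC against P3 (358), 8 for P5 against P4 (98), 70 for DNFB in P2 (402), 0 for DNFB in DC (830), 2 for DNFB in lymph node DC (268), 1 and 37 for lymph node against dermal DC at steady state (4040) and after DNFB (3486), and 1 and 6 for CD64+ lymph node cells against lymph node DC (961) and against P2 (2517). DNFB in P1 was not split, with 2 arrays after DNFB.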
